A study of Homo sapiens with 12 samples.

How the data were processed

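RNA was sequenced from THP-1 cells, a human monocytic leukaemia line that the labels list as macrophages. The 12 samples were grouped by their titles into untreated cells, cells treated with low-density lipoprotein (LDL), cells treated with LL37 and cells treated with LDL plus LL37, with 3 samples in each of the 4 groups. Treatment lasted 24 h, per the labels. The labels do not say whether the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Doses of LDL and LL37 are not given in the sources used here.

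The submitters' processing notes name the aligner STAR and the analysis suite Partek, without versions. The genome build, the annotation, the counting settings, strand and the test behind the p-values are not given in the sources used here. The deposited table is a summary per group. Per the file headers, it holds a least-squares mean for each group, and each group's means summed to 1e+06, so they were read as CPM (counts scaled to that sum) made by the authors, with an offset of 0.0001 that gene values of 0 carry. The columns named for a mixture were taken as LDL plus LL37, since the remaining groups have columns of their own name. Per the file headers, the authors' ratio and signed fold change compare each treated group with untreated cells; the ratio equalled the quotient of the deposited means to within 8.52e-11. The deposited p-value of each gene came with an adjusted p-value, which equalled a Benjamini-Hochberg adjustment over all 14872 genes to within 3.41e-15. The untreated mean appears 3 times with identical values, and the 2 repeats were not used. Values per sample were not analysed here, so no standard deviation, overlap of replicates or check of single libraries is given.

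Depth was read from the low values. A mean of 3 libraries that each hold few counts is a sum of whole multiples of 3 steps, each the worth of 1 count in 1 library divided by 3. For each group, the 3 steps that explained most means under 0.3 CPM, to within 1e-07 CPM, were searched for. They explained 75.4% to 78.1% of these means, against 0.09% to 0.22% of random values. In 5 of 5 simulated groups the search returned the library totals to within 0.1%. The totals cannot be assigned to replicate numbers.

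The design, the gene lists and the naming rule were fixed before the data were examined. For a table of group means and comparisons, that design called for no test and for a description of the authors' values. Counts of changed genes against untreated cells are therefore those of the authors' deposited table at an adjusted p under 0.05. The table has no comparison among treated groups. Tests of these were derived from it, which departs from the fixed design and was decided after seeing the data. The 3 deposited p-values of a gene imply a standard error of its log2 ratio for any assumed number of degrees of freedom. Over 1528 genes with a mean of at least 20 CPM and p under 0.05 in all 3 comparisons, the 3 implied errors of a gene were closest at 14.9 degrees of freedom, with a median disagreement of 0.878%. That is the pattern of 1 shared error per gene on the log2 scale. The implied error was then used for LDL plus LL37 against LDL, LDL plus LL37 against LL37, and the LDL by LL37 interaction, which is the LL37 effect with LDL minus the LL37 effect without it. The error of the interaction is the implied error times the square root of 2, which assumes that all 4 groups share 1 spread. Genes needed a mean of at least 1 CPM over the 4 groups and implied errors that disagreed by at most 0.5 standard errors. Of 12943 genes with that mean, 12916 were tested and 27 were left out, and p-values were adjusted by Benjamini-Hochberg. The log2 ratios are quotients of arithmetic means, which weigh a high library more than a low one.

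The derivation was tested in several ways. For each deposited comparison, its own log2 ratio was tested with the error implied by the other 2, over the 12916 genes. By this, 2353 of 2396 calls for LDL, 7554 of 7600 for LL37 and 6923 of 6974 for LDL plus LL37 were recovered. The degrees of freedom and the choice of genes drew on every comparison, so close recovery was largely built in. It checks the shared error alone and not the derived comparisons. On simulated counts with a gamma-Poisson spread, in a comparison of the interaction over 12830 genes with 100 genes changed per size, limma's own moderated test made 130 calls and the derived test made 128, of which 128 were shared. The derived test recovered 37% of genes with an interaction of 0.5 on the log2 scale and 88% of those with 1, with 2.34% false calls. The simulation gave each gene the same spread in every group and took its p-values from limma. It therefore cannot check whether the authors' data and test meet these assumptions. In the text, an error after ± is the implied standard error of a log2 ratio, and each rests on 3 libraries per group.

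The gene lists were 29 lists of sterol, lipid, inflammatory, interferon, stress, lysosomal, cell cycle, macrophage and progenitor genes, of LL37 receptors and of other cell types. The planned camera test needs values per sample. In its place, chosen after seeing the data, each list was tested with limma's cameraPR on the t-statistics implied by the deposited p-values, over genes with a mean of at least 1 CPM and lists of at least 3 such members, 23 in all. The test is two-sided and compares a list with all other genes. It used a preset inter-gene correlation of 0.01, and p-values were adjusted over the 23 lists within a comparison. An estimated correlation needs values per sample and was not computed, so preset correlations of 0.05 and 0.5 were added. On simulated t-statistics, 0 of 138 unchanged lists and 6 of 6 shifted lists passed. These were drawn without correlation between genes, so they do not check lists whose genes move together. Per-gene p-values were also adjusted over the list alone.

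The genes named in the text follow the fixed rule. Per comparison, these are the 5 largest positive and 5 largest negative log2 ratios among genes with adjusted p under 0.05 and a mean of at least 1 CPM, the 3 members with the smallest p in each of the 5 lists with the smallest list p and at least 1 member past the test, and focus genes, among them ABCA1, IL1B, CD36 and PLIN2. Some genes that the rule takes are not reported here. The rule also asked for groups without overlap, which needs values per sample and was not applied. CAMP, which encodes the LL37 precursor, was a focus gene but is not listed in the authors' deposited table, so it was not analysed here. Exceptions are said to have been chosen after their values were seen. Where a group mean lies under the worth of 3 counts in that group, means are given in place of a ratio.

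Settings fixed beforehand that could be run on group means were a mean of at least 10 CPM, no filter on low values, quantile normalization and a pseudocount of 0.1 CPM. Added after seeing the data were a mean of at least 1 CPM for comparisons against untreated cells, centring on the median log2 ratio of genes with at least 1 CPM, a pseudocount of 1 CPM, an implied error multiplied by 1.2, inclusion of genes whose implied errors disagree, and ranks in the list tests. GC content and length were taken from the longest GENCODE v29 transcript of each symbol, which matched 12443 of 12943 genes; their trend was removed as medians over 20 bins. Symbols were matched to a reference gene table for RNA classes, with 14446 of 14872 found. No coordinates are given, since the authors' build is not given. Correlations between comparisons that share the untreated libraries were set beside 100 simulations without effects. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.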

Results

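RNA was sequenced from THP-1 cells, a human monocytic leukaemia line listed as macrophages in the labels. Cells were left untreated or exposed for 24 h to low-density lipoprotein (LDL), the main cholesterol carrier of plasma, to LL37, the antimicrobial peptide released from human cathelicidin, or to LDL plus LL37. Each of the 4 groups had 3 samples, 12 in all. The authors' deposited table gives 14872 genes with a mean per group in CPM (counts scaled to a sum of 1e+06 per library), and ratios with p-values for each treatment against untreated cells. Comparisons among treated groups and the LDL by LL37 interaction were derived from these p-values for 12916 genes, a step added after seeing the data.

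Library totals of counts on the listed genes, read from the low values, were 17.3, 20.5 and 23.3 M (M, 1e+06 counts) for untreated cells and 19.3, 20.7 and 25.7 M for LDL. They were 22.8, 23.5 and 25.4 M for LL37 and 17.6, 20.6 and 25.1 M for LDL plus LL37. Over the 3 libraries of a group, 3 counts equalled 0.0491, 0.0457, 0.0419 and 0.0473 CPM in the same order, a floor that covers counting error alone. Nothing in the labels says that the samples of a group were separate cultures, so the p-values measure only the spread between these samples. Values after ± are standard errors implied by the deposited p-values. How many samples shared a direction was not analysed here, since the authors' deposited table holds group means.

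Markers of other cell types were low beside SPP1, the most abundant of the macrophage maturation markers, which summed to 26459, 25514, 15666 and 14547 CPM in untreated, LDL, LL37 and LDL plus LL37 cells in the authors' deposited table. In the same order, fibroblast markers summed to 27.9, 19.8, 38.8 and 14.4 CPM in the authors' deposited table. Epithelial markers summed to 21.2, 22.2, 23.7 and 23.2 CPM, lymphoid markers to 13.4, 12.3, 31.5 and 13.3 CPM and endothelial markers to 12.025, 12.232, 5.79 and 5.11 CPM in the authors' deposited table. Of 6 erythroid markers and of 13 mitochondrially encoded transcripts, the planned sign of RNA quality, 0 were listed in the authors' deposited table. RNA quality could therefore not be judged from these transcripts. Ribosomal RNA genes held 1.88%, 1.27%, 1.53% and 1.37% of all CPM in the authors' deposited table, and the 10 most abundant genes 8.50%, 9.08%, 7.15% and 8.06%.

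LDL alone lowered genes of sterol and fatty acid synthesis. Of 20 cholesterol synthesis genes in the authors' deposited table, 19 fell and 1 rose, both over all genes and when adjusted over the list alone (median log2 ratio -0.58; list adjusted p = 1.60e-45). HMGCS1, which makes the precursor of mevalonate, had a log2 ratio of -0.96 ± 0.051, DHCR7, which completes cholesterol, -1.22 ± 0.066 and CYP51A1, a sterol demethylase, -0.75 ± 0.052 in the authors' deposited table. The gene that rose was PMVK, a mevalonate pathway kinase named after its values were seen, at 0.32 in the authors' deposited table.

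All 10 fatty acid synthesis genes fell with LDL in the authors' deposited table, also when adjusted over the list alone (median -0.66; list adjusted p = 2.88e-38). SCD, a fatty acid desaturase, was at -1.43 ± 0.052, FADS2, another desaturase, at -2.21 ± 0.20 and ACSL3, which activates fatty acids, at -0.59 ± 0.052 in the authors' deposited table. Of 12 LXR targets and sterol efflux genes, 11 fell and 1 did not pass in the authors' deposited table, and 12 fell when adjusted over the list alone (median -0.62; list adjusted p = 1.61e-32). ABCA1, which exports cholesterol, was at -0.84 ± 0.067 and SREBF1, a regulator of lipid synthesis, at -0.81 ± 0.079 in the authors' deposited table. SCD and SREBF1 stand in both lists.

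Inflammatory genes were lower with LDL and lysosomal genes slightly higher. Of 19 cytokine and NF-kB target genes in the authors' deposited table, 11 fell and 8 did not pass, with 13 lower when adjusted over the list alone (median -0.38; list adjusted p = 2.42e-07). IL1B, a cytokine of fever and inflammation, was at -0.64 ± 0.072, BIRC3, an inhibitor of apoptosis, at -1.11 ± 0.16 and IL1RN, which blocks the IL-1 receptor, at -0.74 ± 0.12 in the authors' deposited table. Of 20 lysosomal genes, 7 rose and 13 did not pass in the authors' deposited table, with 10 higher when adjusted over the list alone (median 0.14; list adjusted p = 5.48e-07). GPNMB, a glycoprotein of endosomes and lysosomes, was at 0.41 ± 0.044, and HEXA, a subunit of beta-hexosaminidase, at 0.24 ± 0.051 in the authors' deposited table. Of 15 antigen presentation genes, 3 rose, 1 fell and 11 did not pass in the authors' deposited table, with 5 and 1 over the list alone (median 0.21 and mean -0.41 over all 15). The list test, run on the 13 of them with a mean of at least 1 CPM, passed as higher (median 0.21; list adjusted p = 0.00544).

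Proliferation and chemokine genes were also lower with LDL. Of 20 cell cycle genes, 12 fell and 8 did not pass in the authors' deposited table, with 14 lower over the list alone (median -0.36; list adjusted p = 7.30e-07). Of 15 chemokines, 6 fell, 1 rose and 8 did not pass in the authors' deposited table, as over the list alone (median -0.52; list adjusted p = 9.19e-04). Of 14 scavenger receptors, 4 rose, 2 fell and 8 did not pass in the authors' deposited table, with 6 and 2 over the list alone (list adjusted p = 0.00715). No interferon-stimulated gene of 20 passed in the authors' deposited table, nor when adjusted over the list alone. Their list test was not passed (list adjusted p = 0.121), but was passed as higher on ranks (adjusted p = 0.0227). Of 3 listed metallothioneins, 2 fell and 1 did not pass in the authors' deposited table, with 3 lower over the list alone. Only 1 of them had a mean of at least 1 CPM.

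The strongest rises with LDL in the authors' deposited table were TGM3, a transglutaminase, at 1.68 ± 0.39, CA12, a carbonic anhydrase, at 1.44 ± 0.24, CD72 at 1.27 ± 0.22, GAS6-DT at 1.26 ± 0.25 and HK3, a hexokinase, at 1.23 ± 0.23. CCL1, a chemokine, was listed at 0 with LDL in the authors' deposited table. MT2A, a metallothionein that binds zinc, fell to -2.96 ± 0.34, CYP26B1, which degrades retinoic acid, to -2.79 ± 0.33 and VCAM1, an adhesion molecule, to -1.82 ± 0.21 in the authors' deposited table. PLIN2, which coats lipid droplets, was at 0.17 ± 0.048 (adjusted p = 0.0305, and adjusted p = 0.0945 after quantile normalization and 0.0983 with an implied error 1.2 times as large) and CD36, a scavenger receptor, was at -0.07 ± 0.072 (adjusted p = 0.594) in the authors' deposited table. In all, 2263 genes changed with LDL, 832 higher and 1431 lower, and 61 of them changed at least 2-fold with a mean of at least 1 CPM, 11 higher and 50 lower, in the authors' deposited table. The share that was higher was 36.8%, against 55.4% after centring and 51.8% after quantile normalization, and 923 genes passed with an implied error 1.2 times as large. Of 13 lists past the list test, 3 passed with a preset correlation of 0.5: cholesterol synthesis, LXR targets and fatty acid synthesis.

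**Figure D1:**
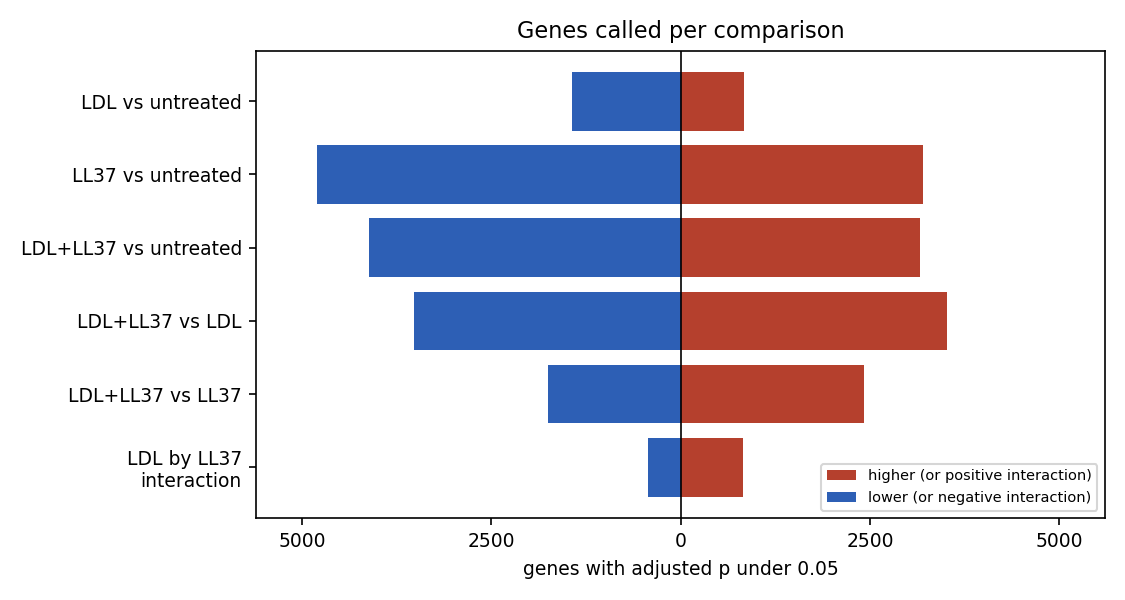
Bars give the number of genes that passed the test in each of the 6 comparisons, higher (or positive interaction) to the right in red and lower (or negative) to the left in blue. LL37 against untreated cells had the most changed genes and the interaction the fewest.

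LL37 alone raised cytokines, chemokines and interferon-stimulated genes. Of 19 cytokine and NF-kB target genes in the authors' deposited table, 18 rose and 1 did not pass, as when adjusted over the list alone (median log2 ratio 1.81; list adjusted p = 9.67e-33). IL1B was at 3.11 ± 0.072, from 799.93 to 6922.5 CPM, SOD2, a mitochondrial superoxide dismutase, at 2.87 ± 0.079 and TNF, a cytokine, at 2.53 ± 0.082 in the authors' deposited table. Of 15 chemokines, 13 rose and 2 did not pass in the authors' deposited table, as when adjusted over the list alone (median 3.42; list adjusted p = 3.31e-25). CXCL8, which attracts neutrophils, was at 3.42 ± 0.11, CCL20, which attracts lymphocytes and dendritic cells, at 3.31 ± 0.11 and CCL5 at 1.97 ± 0.064 in the authors' deposited table.

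All 20 interferon-stimulated genes rose with LL37 in the authors' deposited table, also when adjusted over the list alone (median 2.76; list adjusted p = 2.70e-11). OAS3, a sensor of viral RNA, was at 2.65 ± 0.17 and ISG15, a ubiquitin-like protein, at 2.76 ± 0.21 in the authors' deposited table. Of 14 NRF2 and oxidative stress genes, 11 rose and 3 did not pass in the authors' deposited table, as when adjusted over the list alone (median 0.49, and 0.42 over the 13 genes in the list test; list adjusted p = 1.67e-08). SLC7A11, a cystine transporter, was at 2.56 ± 0.086, GCLC, an enzyme of glutathione synthesis, at 1.12 ± 0.050 and FTH1, the heavy chain of ferritin, at 1.40 ± 0.077 in the authors' deposited table. Of 18 immediate early genes, 12 rose, 2 fell and 4 did not pass in the authors' deposited table, as when adjusted over the list alone (median 1.21, and 0.82 over the 16 genes in the list test; list adjusted p = 1.55e-07). IER3 was at 2.57 ± 0.12, the transcription factor EGR1 at 1.48 ± 0.081 and DUSP1, a phosphatase of MAP kinases, at 2.13 ± 0.13 in the authors' deposited table.

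Progenitor and proliferation genes were lower with LL37. All 9 myeloid progenitor markers fell in the authors' deposited table, also when adjusted over the list alone (median -0.92, and -0.90 over the 8 genes in the list test; list adjusted p = 4.85e-06), and of 20 cell cycle genes 17 fell and 3 did not pass, with 18 lower over the list alone (median -0.46; list adjusted p = 0.0297, and adjusted p = 0.103 with a preset correlation of 0.05). Of 20 cholesterol synthesis genes, 4 rose, 11 fell and 5 did not pass in the authors' deposited table, as when adjusted over the list alone, and the list test was not passed (list adjusted p = 0.163). Of 13 listed genes reported as LL37 receptors or their partners, 4 rose, 6 fell and 3 did not pass in the authors' deposited table, as when adjusted over the list alone (list adjusted p = 0.741).

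Hypoxia and matrix metalloproteinase genes were mostly higher with LL37. Of 15 hypoxia and glycolysis genes, 12 rose, 1 fell and 2 did not pass in the authors' deposited table, and of 15 matrix metalloproteinase genes 11 rose and 4 fell, both as over the list alone (list adjusted p = 4.08e-07 and 2.93e-06). Of 17 genes of the unfolded protein and ATF4 response, 12 rose, 2 fell and 3 did not pass in the authors' deposited table, and of 16 macrophage maturation markers 3 rose, 8 fell and 5 did not pass, both as over the list alone (list adjusted p = 0.0218 and 0.0353, and adjusted p = 0.0885 and 0.103 with a preset correlation of 0.05). The maturation list also did not pass on ranks (adjusted p = 0.379). The inflammasome and p53 lists did not pass the list test. Of 12 inflammasome genes, 3 rose, 5 fell and 4 did not pass in the authors' deposited table, with 3 and 6 over the list alone (list adjusted p = 0.0520). Of 13 p53 targets, 3 rose, 5 fell and 5 did not pass in the authors' deposited table, as over the list alone (list adjusted p = 0.680).

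The strongest rises with LL37 in the authors' deposited table were PTGES, which makes prostaglandin E2, at 5.57 ± 0.50, TNFAIP6, a hyaluronan-binding protein, at 5.23 ± 0.35, LOC730338 at 5.21 ± 0.50 and CCL1 at 5.03 ± 1.01. CSF3, the growth factor of neutrophils, had means of 0.0469 CPM in untreated cells and 4.64 CPM with LL37 in the authors' deposited table. The strongest falls were FOLH1, a glutamate carboxypeptidase, at -4.99 ± 0.37, VIPR1, a neuropeptide receptor, at -4.85 ± 0.25, STYXL2 at -4.72 ± 0.34 and SELENOP, a selenium transport protein, at -4.68 ± 0.22 in the authors' deposited table. LYVE1, a hyaluronan receptor, had means of 4.45 CPM in untreated cells and 0.0147 CPM with LL37 in the authors' deposited table. CD36 fell to -1.31 ± 0.072, and PLIN2 to -0.35 ± 0.048, while ABCA1 rose to 0.74 ± 0.067 in the authors' deposited table. In all, 7997 genes changed, 3199 higher and 4798 lower (3917 and 3935 after quantile normalization, 3990 and 4070 after centring), and 1378 of them changed at least 2-fold with a mean of at least 1 CPM, 494 higher and 884 lower, in the authors' deposited table. Of 12 lists past the list test, 2 passed with a preset correlation of 0.5: cytokines and chemokines; the interferon-stimulated list, with an implied error 3.05 times that of random lists of like mean, was not among them.

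**Figure D2:**
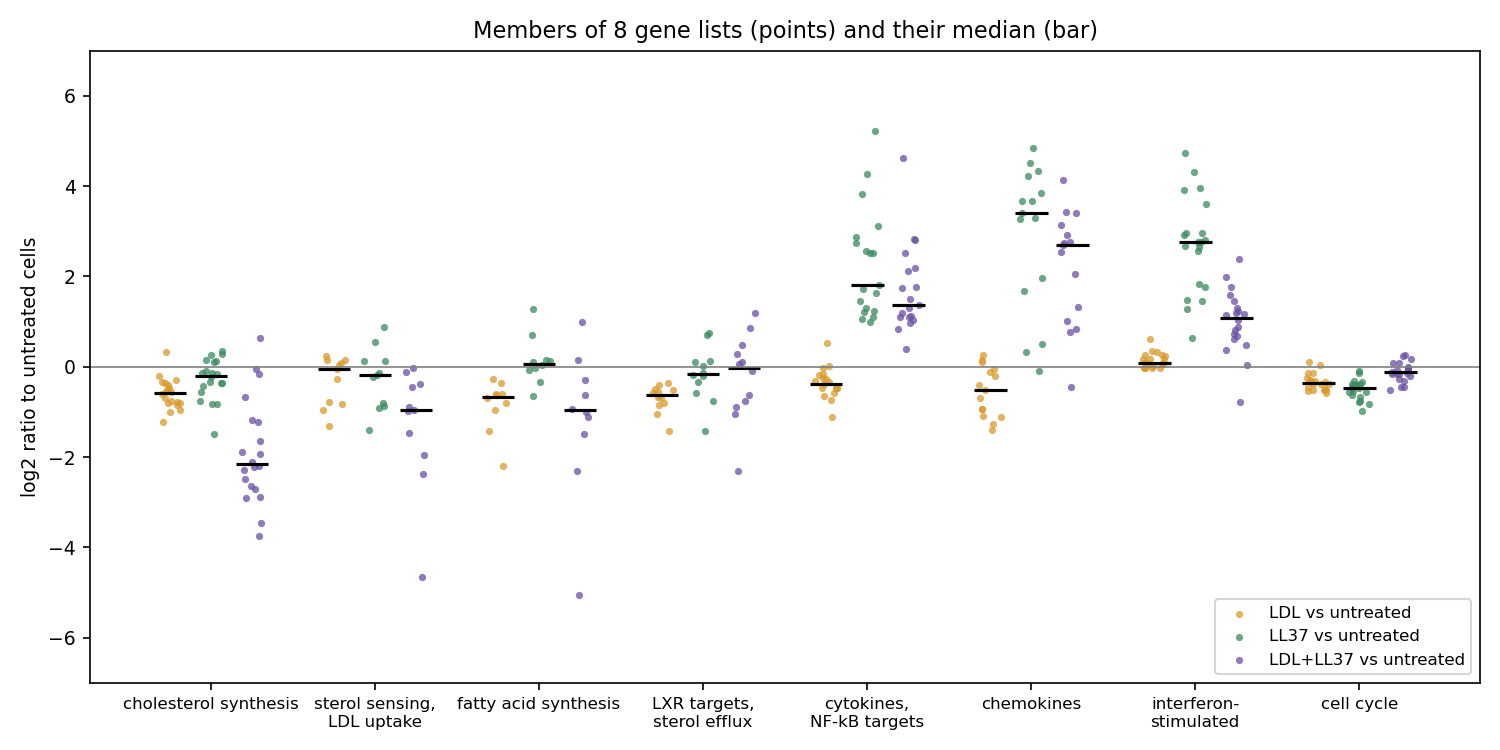
Log2 ratio to untreated cells of each gene in 8 lists for each treatment; each point is a gene and each black bar the list's median. The medians of the cytokine, chemokine and interferon lists lay above 0 with LL37 and with LDL plus LL37, and 1 point, IL6 with LDL, lies outside the axis.

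LDL plus LL37 lowered cholesterol synthesis genes and raised inflammatory genes against untreated cells. Of 20 cholesterol synthesis genes in the authors' deposited table, 18 fell, 1 rose and 1 did not pass, as when adjusted over the list alone (median log2 ratio -2.16; list adjusted p = 1.50e-79). DHCR7 was at -3.46 ± 0.066 and FDFT1, squalene synthase, at -2.30 ± 0.048 in the authors' deposited table. Of 11 sterol sensing and LDL uptake genes, 9 fell and 2 did not pass in the authors' deposited table, as when adjusted over the list alone (median -0.96; list adjusted p = 3.81e-18). SREBF2, the main regulator of sterol synthesis, was at -1.96 ± 0.055 and STARD4, a sterol transfer protein, at -2.37 ± 0.075 in the authors' deposited table. Of 10 fatty acid synthesis genes, 8 fell and 2 rose in the authors' deposited table, as when adjusted over the list alone (median -0.97; list adjusted p = 1.89e-10), with SCD at -2.32 ± 0.052, FADS2 at -5.06 ± 0.20 and ACSL3 at -1.11 ± 0.052.

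Of 19 cytokine and NF-kB target genes, 18 rose and 1 did not pass with LDL plus LL37 in the authors' deposited table, as when adjusted over the list alone (median 1.36; list adjusted p = 2.74e-25). SOD2 was at 2.82 ± 0.079, IL1B at 2.12 ± 0.072 and NFKBIA, an inhibitor of NF-kB, at 1.76 ± 0.080 in the authors' deposited table. Of 15 chemokines, 13 rose and 2 did not pass in the authors' deposited table, with 13 higher and 1 lower over the list alone (median 2.70, and 2.73 over the 13 genes in the list test; list adjusted p = 3.31e-20), including CXCL1 at 3.41 ± 0.13, CXCL8 at 2.70 ± 0.11 and CCL3 at 2.91 ± 0.12. Of 20 interferon-stimulated genes, 16 rose, 1 fell and 3 did not pass in the authors' deposited table, as when adjusted over the list alone (median 1.09; list adjusted p = 0.0110, and adjusted p = 0.0556 with a preset correlation of 0.05). The interferon-stimulated gene that fell was USP18, which removes ISG15 from proteins and was named after its values were seen, at -0.78 in the authors' deposited table.

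The strongest rises with LDL plus LL37 in the authors' deposited table were TNFAIP6 at 4.61 ± 0.35, PTGES at 4.50 ± 0.50, LOC730338 at 4.15 ± 0.50 and CCL4, a chemokine, at 4.13 ± 0.21. CCL4 has a near-identical copy, CCL4L2, so reads may be shared between them. CSF3 had means of 0.0469 and 1.61 CPM and LYVE1 of 4.45 and 0.0836 CPM in untreated and LDL plus LL37 cells in the authors' deposited table. FOLH1 fell to -5.07 ± 0.37 and MSMO1, a sterol oxidase, to -3.76 ± 0.082 in the authors' deposited table. ABCA1 was at 0.85 ± 0.067, PLIN2 at 0.47 ± 0.048 and CD36 at -0.36 ± 0.072, all of which passed the test in the authors' deposited table. In all, 7276 genes changed, 3162 higher and 4114 lower (3792 and 3404 after quantile normalization, 3531 and 3752 after centring), and 1098 of them changed at least 2-fold with a mean of at least 1 CPM, 366 higher and 732 lower, in the authors' deposited table. Of 14 lists past the list test, 5 passed with a preset correlation of 0.5: cholesterol synthesis, sterol sensing, fatty acid synthesis, cytokines and chemokines.

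Against LDL alone, LDL plus LL37 lowered sterol genes further and raised inflammatory genes. Of 20 cholesterol synthesis genes, 17 fell, 2 rose and 1 did not pass, as when adjusted over the list alone (median log2 ratio -1.44; list adjusted p = 1.99e-35), with FDFT1 at -1.73 ± 0.048 and MSMO1 at -2.92 ± 0.082. Of 11 sterol sensing genes, 10 fell and 1 did not pass, as over the list alone (median -0.50; list adjusted p = 5.35e-11), with SREBF2 at -1.68 ± 0.055 and STARD4 at -1.55 ± 0.075. All 16 tested cytokine and NF-kB target genes rose, also over the list alone (median 1.49; list adjusted p = 1.67e-34), with SOD2 at 3.08 ± 0.079, IL1B at 2.76 ± 0.072 and TNF at 2.21 ± 0.082. Of 13 tested chemokines, 12 rose and 1 fell, as over the list alone (median 3.53; list adjusted p = 1.23e-25), with CCL20 at 3.65 ± 0.11, CXCL8 at 3.63 ± 0.11 and CCL3 at 3.32 ± 0.12. Of 13 tested NRF2 genes, 10 rose and 3 did not pass, with 12 higher over the list alone (median 0.49; list adjusted p = 1.43e-07), with SLC7A11 at 2.66 ± 0.086, GCLC at 1.099 ± 0.050 and FTH1 at 1.43 ± 0.077. Of 18 tested interferon-stimulated genes, 12 rose, 1 fell and 5 did not pass, with 13 and 1 over the list alone (median 0.79). Their list test was not passed (list adjusted p = 0.0859), but was on ranks (adjusted p = 0.00306).

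CCL4 at 5.21 ± 0.21, CCL4L2 at 4.23 ± 0.18 and BMP6, a growth factor that governs iron balance, at 4.23 ± 0.26 were the strongest rises against LDL, beside CCL1, which was listed at 0 with LDL, and CSF3, with means of 0.0131 and 1.61 CPM. The strongest falls were FOLH1 at -4.33 ± 0.37, ZBTB16, a transcriptional repressor, at -3.80 ± 0.31, VIPR1 at -3.52 ± 0.25, GPR55, a lipid receptor, at -3.48 ± 0.40 and ANK1, ankyrin of the membrane skeleton, at -3.44 ± 0.26. ABCA1 rose to 1.69 ± 0.067 and PLIN2 to 0.30 ± 0.048, and CD36 fell to -0.29 ± 0.072. In all, 7041 of 12916 genes changed, 3520 higher and 3521 lower, and 1118 of them at least 2-fold, 408 higher and 710 lower. Of 11 lists past the list test, 4 passed with a preset correlation of 0.5: cholesterol synthesis, sterol sensing, cytokines and chemokines.

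Against LL37 alone, LDL plus LL37 lowered sterol, fatty acid, interferon-stimulated, cytokine and chemokine genes and raised lysosomal genes. The cytokine, chemokine and lysosomal lists did not pass with a preset correlation of 0.5 (adjusted p = 0.225, 0.310 and 0.0941). Of 20 cholesterol synthesis genes, 19 fell and 1 rose, as when adjusted over the list alone (median log2 ratio -1.89; list adjusted p = 5.08e-171), with DHCR7 at -3.12 ± 0.066 and MSMO1 at -3.60 ± 0.082. All 10 fatty acid synthesis genes fell, also over the list alone (median -0.97; list adjusted p = 1.43e-39), with SCD at -1.98 ± 0.052, FADS2 at -4.41 ± 0.20 and ACSL3 at -1.03 ± 0.052. Of 11 sterol sensing genes, 3 rose, 6 fell and 2 did not pass, as over the list alone (median -0.16; list adjusted p = 2.50e-29, and adjusted p = 0.280 on ranks), with INSIG1, which retains sterol regulators in the endoplasmic reticulum, at -2.34 ± 0.051 and STARD4 at -2.49 ± 0.075.

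All 18 tested interferon-stimulated genes were lower with LDL plus LL37 than with LL37 alone, also over the list alone (median -1.63; list adjusted p = 1.95e-14), with OAS1 at -1.41 ± 0.15 and OAS3 at -1.49 ± 0.17. The implied error of this list was 3.05 times that of random lists of like mean, and single libraries could not be checked. All 20 listed genes had a mean of at least 1 CPM, so those not tested were left out because their implied errors disagreed. Over all genes, 27 of 12943 were left out for that reason, a smaller share than in this list. Of 13 tested chemokines, 9 fell, 1 rose and 3 did not pass, with 10 and 1 over the list alone (list adjusted p = 4.80e-04). Of 16 tested cytokine and NF-kB target genes, 7 fell and 9 did not pass, with 8 lower over the list alone (median -0.26; list adjusted p = 1.03e-05). IL1B was at -0.99 ± 0.072. Of 20 lysosomal genes, 14 rose and 6 did not pass, as over the list alone (median 0.35; list adjusted p = 1.18e-10), with GPNMB at 0.91 ± 0.044 and CTSA, a protective protein of lysosomal enzymes, at 0.49 ± 0.044. Of 20 cell cycle genes 16 rose and 4 did not pass, with 18 higher over the list alone (median 0.39; list adjusted p = 4.80e-04). Of 16 lipid storage and PPAR target genes, 9 rose, 2 fell and 5 did not pass, with 11 and 2 over the list alone (median 0.22; list adjusted p = 3.10e-09). Of 14 scavenger receptors, 12 rose and 2 fell, as over the list alone (median 0.46; list adjusted p = 3.99e-07). The LXR list passed as lower (list adjusted p = 0.0321), with a mean of -0.07 and a median of 0.18. It did not pass with a preset correlation of 0.05 (adjusted p = 0.0753) or on ranks, where its sign turned (adjusted p = 0.876). It had 4 genes that rose, 3 that fell and 5 that did not pass, as over the list alone.

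STYXL2 at 2.62 ± 0.34, RNASE1, a secreted ribonuclease, at 2.43 ± 0.33, PDK4, which restrains glucose oxidation, at 2.42 ± 0.20, KLRC1, a lectin-like receptor, at 2.19 ± 0.29 and P2RY12, a receptor for ADP, at 1.98 ± 0.22 were the strongest rises against LL37. MT2A fell to -3.56 ± 0.34. CD36 rose to 0.95 ± 0.072 and PLIN2 to 0.82 ± 0.048, and ABCA1 was at 0.11 ± 0.067 (adjusted p = 0.214). In all, 4181 of 12916 genes changed, 2427 higher and 1754 lower (2116 and 2015 after centring), and 309 of them at least 2-fold, 114 higher and 195 lower. Of 17 lists past the list test, 4 passed with a preset correlation of 0.5: cholesterol synthesis, sterol sensing, fatty acid synthesis and interferon-stimulated genes.

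The interaction, which is the LL37 effect with LDL minus the LL37 effect without it, was negative for sterol synthesis and interferon-stimulated genes and positive for cell cycle and LXR target genes. Of 20 cholesterol synthesis genes, 17 had a negative interaction and 3 did not pass, with 18 over the list alone (median -1.08; list adjusted p = 2.11e-107), with MSMO1 at -2.76 ± 0.12 and DHCR7 at -1.90 ± 0.094. Of 18 tested interferon-stimulated genes, 17 were negative and 1 did not pass, with 18 over the list alone (median -1.86; list adjusted p = 6.69e-27, and adjusted p = 8.80e-04 with a preset correlation of 0.5). IFITM3, which blocks virus entry, was at -1.14 ± 0.15 and OAS2 at -2.23 ± 0.33. The interferon-stimulated list had an implied error 3.05 times that of random lists of like mean. Of its 20 genes, those not tested were left out because their implied errors disagreed. Of 11 sterol sensing genes, 5 were negative, 2 positive and 4 did not pass, as over the list alone (median -0.12; list adjusted p = 9.14e-24, and adjusted p = 0.106 on ranks), with INSIG1 at -1.37 ± 0.072 and SREBF2 at -1.45 ± 0.078.

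Of 20 cell cycle genes, 16 had a positive interaction and 4 did not pass, with 18 over the list alone (median 0.75; list adjusted p = 2.94e-17), with MCM6 and MCM3, subunits of the replicative helicase, at 0.74 ± 0.086 and 0.77 ± 0.11 and RRM2, a subunit of ribonucleotide reductase, at 0.84 ± 0.12. Of 12 LXR targets, 7 were positive, 1 negative and 4 did not pass, with 8 and 1 over the list alone (median 0.73; list adjusted p = 3.15e-11), with ABCG1, a sterol exporter, at 1.37 ± 0.11, ABCA1 at 0.95 ± 0.094 and NR1H3, which encodes LXR alpha, at 1.08 ± 0.11. CD36 was at 1.01 ± 0.10, PLIN2 at 0.65 ± 0.068 and IL1B at -0.35 ± 0.10 (adjusted p = 0.0423). IL1B did not pass after quantile normalization (adjusted p = 0.219) or with an implied error 1.2 times as large (adjusted p = 0.136). Of 13 tested chemokines, 1 had a negative interaction and 12 did not pass, with 2 over the list alone (list adjusted p = 0.168). The positive interactions of the cell cycle and LXR lists do not mean that LDL plus LL37 raised them above untreated cells. Against untreated cells, 1 cell cycle gene rose, 4 fell and 15 did not pass in the authors' deposited table (list adjusted p = 0.676). Of the LXR targets, 4 rose, 5 fell and 3 did not pass (list adjusted p = 0.0678).

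VCAM1 at 2.04 ± 0.29 and KLRC1 at 1.92 ± 0.41 had positive interactions, as did the readthrough loci SPECC1L-ADORA2A at 2.31 ± 0.67 and ARHGAP11A-SCG5 at 2.07 ± 0.46, whose reads can come from their component genes. SPECC1L-ADORA2A did not pass after quantile normalization (adjusted p = 0.0565), after centring (adjusted p = 0.0518) or with an implied error 1.2 times as large (adjusted p = 0.137). CCL1 passed with a positive value, which rests on its mean listed at 0 with LDL and turned negative with a pseudocount of 0.1 CPM (-1.17). IFI44L at -2.96 ± 0.54, MX1, an antiviral GTPase, at -2.70 ± 0.66 and XAF1 at -2.38 ± 0.38 were among the strongest negative interactions, and MX1 did not pass with an implied error 1.2 times as large (adjusted p = 0.0702). In all, 1258 of 12916 genes passed, 830 positive and 428 negative, and 213 of them at least 2-fold, 109 positive and 104 negative. The share that was positive was 66.0%, against 46.9% after centring and 53.6% after quantile normalization, and 575 genes passed with an implied error 1.2 times as large. Of 13 lists past the list test, 6 passed with a preset correlation of 0.5: cholesterol synthesis, sterol sensing, LXR targets, fatty acid synthesis, interferon-stimulated genes and cell cycle.

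**Figure D3:**
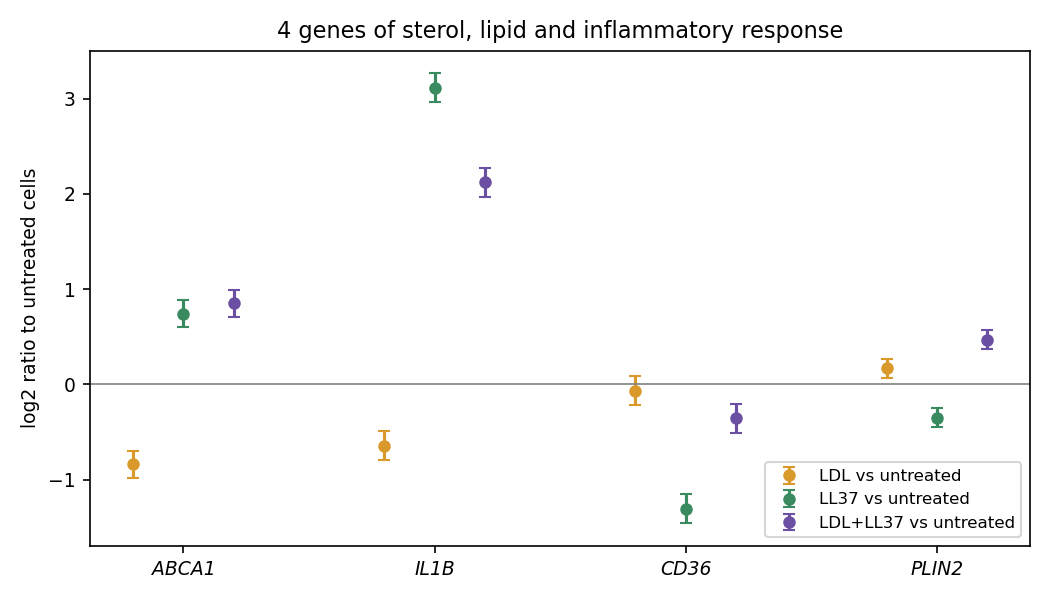
Log2 ratio to untreated cells of 4 genes for each treatment; error bars are 95% intervals from the implied standard error. IL1B was highest and CD36 lowest with LL37, and ABCA1 lay below 0 with LDL and above 0 with LL37 and with LDL plus LL37.

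The LL37 effects with and without LDL were correlated across genes. The log2 ratios of LDL plus LL37 against LDL and of LL37 against untreated cells, which share no library, had a Pearson correlation of 0.872 and a Spearman correlation of 0.822 over 12943 genes. Of 7531 genes changed by LL37 alone, 92.8% had the same sign with LDL (81.9% over all genes), and 5491 passed in both with the same sign and 137 with opposite signs, against 4097 shared calls if independent. The LDL effect with and without LL37 had a Pearson correlation of 0.465 and a Spearman correlation of 0.466. Of 2233 genes changed by LDL alone, 83.9% had the same sign with LL37 (67.3% over all genes), and 1218 passed in both with the same sign and 119 with opposite signs, against 721 if independent. For both effects, the derived test took its error per gene from the deposited p-values. Part of the excess over independence may therefore come from genes with a small or large error in both tests. The Pearson correlation of the LDL effect was 0.284 without a filter on low values.

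**Figure D4:**
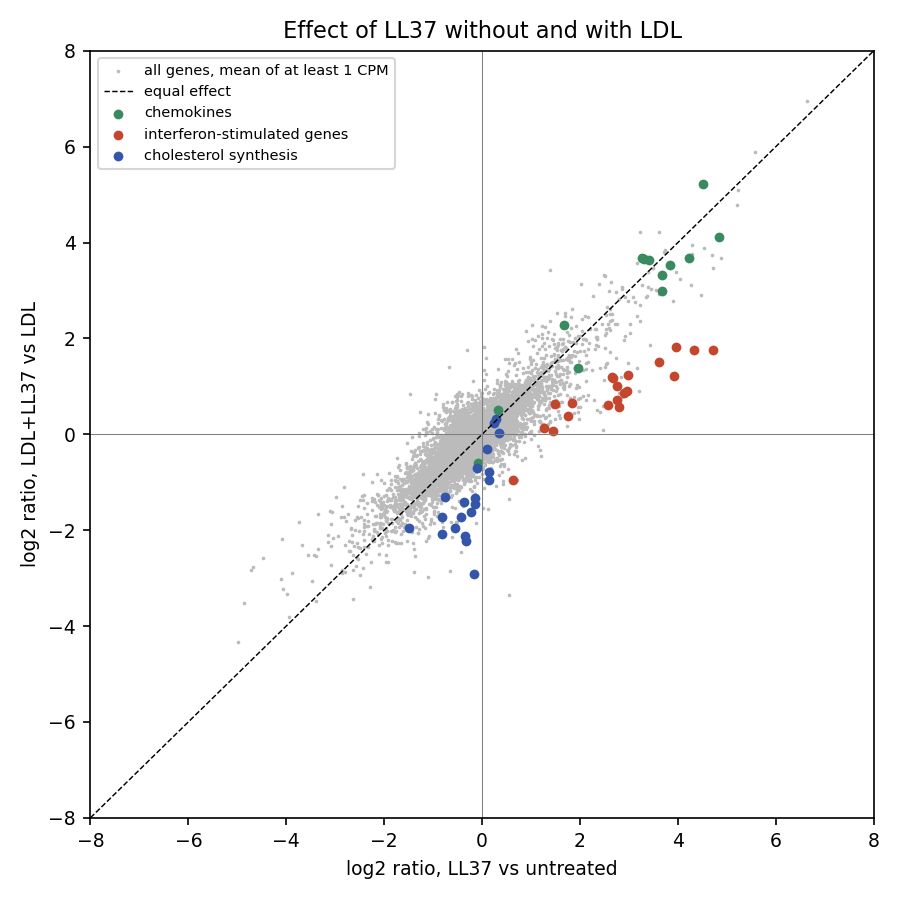
Log2 ratio of LL37 against untreated cells and of LDL plus LL37 against LDL; each point is a gene with a mean of at least 1 CPM, the dashed line marks equal effects and 3 lists are coloured. Interferon-stimulated and most cholesterol synthesis genes lay below the line, and CCL1 and LYVE1 lie outside the axes.

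Comparisons against the same untreated libraries are correlated without any effect, with a simulated Pearson correlation of 0.501 for LDL and LL37, 0.5004 for LDL and LDL plus LL37 and 0.502 for LL37 and LDL plus LL37. These values follow from the shared control by construction and are no yardstick for measured correlations, which also hold real effects. The measured correlations were -0.149, 0.116 and 0.843 over 12916 genes. The covariances were -0.0273, 0.0185 and 0.348, against 0.00854, 0.00851 and 0.00852 without effect. LDL and LL37 shared 148 higher and 426 lower genes, against 195 and 487 if independent, and 984 genes passed with opposite signs. LDL and LDL plus LL37 shared 333 higher and 564 lower genes, against 195 and 416, and LL37 and LDL plus LL37 shared 2208 and 3024, against 727 and 1313. In these pairs, 563 and 139 genes passed with opposite signs. A value under independence was not computed for calls of opposite sign in any pair. Part of the excess of calls of the same sign in the pairs with LDL plus LL37 may come from the shared controls, and the untreated libraries could not be split.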

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

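The tests of scaling for sterol and interferon genes and of a weaker LL37 response as a whole were chosen only after the result was seen.

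The LDL by LL37 interaction passed for 1258 genes. Among focus genes it was 0.95 for ABCA1, -0.35 for IL1B, 1.01 for CD36 and 0.65 for PLIN2. List medians that went with a list test past its threshold were -1.08 for cholesterol synthesis, -1.86 for interferon-stimulated genes, -0.12 for sterol sensing, 0.75 for cell cycle, 0.73 for LXR targets and -0.31 for fatty acid synthesis. They were 0.26 for lipid storage (adjusted p = 0.0546 on ranks), -0.33 for matrix metalloproteinases, 0.32 for scavenger receptors, 0.20 for lysosome, -0.26 for immediate early genes, -0.11 for hypoxia and -0.96 for fibroblast markers, a list of 3 tested genes led by PDGFRA.

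Sterol synthesis genes were lower with LDL plus LL37 than the sum of the separate effects. After centring on the median of all genes the median interaction was -1.14 (95% interval over genes -1.37 to -0.64), and after removal of the trend with GC content and transcript length it was -1.18 (-1.40 to -0.64). The trend therefore does not account for it. The median interaction over genes with a mean of at least 1 CPM was only 0.06, so centring could hardly move the list. A shift of that size does not account for the fall, and centring tests no other kind of scaling. A candidate explanation is stronger repression of sterol-regulated transcription as a whole. A second list of 8 genes of that regulation had a median of -0.25 (-1.16 to 0.01), which leaves it open. The intervals in this paragraph and the next come from 10000 resamplings of the genes of a list. They hold no spread between libraries and treat genes that move together as separate, so they may be too narrow. LDL uptake was not measured.

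Interferon-stimulated genes rose less with LL37 when LDL was present. The share of the LL37 response left with LDL was taken per gene on the log2 scale. It is the log2 ratio of LDL plus LL37 against LDL divided by that of LL37 against untreated cells. Its median was 30.7% in 18 interferon-stimulated genes and 107% in 28 chemokine, cytokine and NF-kB target genes, a difference of 0.761 as shares (0.524 to 0.853). Shares of the gain in CPM would differ. By these group means, an equally weaker response of these lists does not account for it. The interval over genes may be too narrow, since interferon-stimulated genes had an implied error 3.05 times that of random lists of like mean. Single libraries could not be checked. Of 20 interferon-stimulated genes, those outside the 18 were left out because their implied errors disagreed. LDL alone had lowered the chemokine list and the cytokine and NF-kB target list. Directly against LL37 alone, these lists were also lower with LDL plus LL37 (list adjusted p = 4.80e-04 and 1.03e-05). Of other lists that LL37 raised, immediate early genes had 6 negative of 16, matrix metalloproteinases 5 negative and 2 positive of 15 and hypoxia 1 of 14. These 3 lists passed the main list test of the interaction, with medians of -0.26, -0.33 and -0.11. None of them passed with a preset correlation of 0.5 (adjusted p = 0.325, 0.271 and 0.325), against adjusted p = 8.80e-04 for interferon-stimulated genes. NRF2 genes had 1 negative of 13, unfolded protein genes 2 positive of 17 and antigen presentation genes 0 of 13, and these lists did not pass. A weaker response in some lists beyond interferon-stimulated genes is thus not excluded. The median interaction of interferon-stimulated genes was -1.92 (-2.16 to -1.49) after centring and -1.91 (-2.18 to -1.46) after removal of the GC and length trend, and its source stays open. Centring again moved all genes by the same small amount.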

How the results depend on the processing

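The settings of the implied error, the preset correlations, ranks, centring, the pseudocount of 1 CPM and the filter at 1 CPM against untreated cells were chosen only after the result was seen.

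No paired analysis was possible because the deposited table holds group means and no values per sample. For the same reason, RLE and upper-quartile size factors, DESeq2 and voom type tools, limma without trend, a replicate block, fits of only the compared groups, leaving out each sample, fry, an estimated correlation and other splits of the samples were not run, and a pseudocount of 0.1 CPM was not run for counts of genes. Changed genes ranged from 2102 to 2397 for LDL over the settings run, apart from 923 with the implied error multiplied by 1.2, and from 1057 to 1259 for the interaction, apart from 575 with that error. They ranged from 5655 to 8060 for LL37, 5325 to 7283 for LDL plus LL37, 5370 to 7336 against LDL and 2918 to 4185 against LL37. The Pearson correlation of the LL37 effect was 0.890 at a mean of at least 10 CPM and 0.782 without a filter, and that of the LDL effect 0.530 and 0.284. With a preset correlation of 0.5, lists past the test numbered 3 for LDL, 2 for LL37, 5 for LDL plus LL37, 4 against LDL, 4 against LL37 and 6 for the interaction. Of 949 alternative values of 165 values taken by the naming rule, 866 stayed alike (in call and sign, or in size alone with a pseudocount, where no test was run), 9 lost the call (CCL1, SPECC1L-ADORA2A, MX1 and IL1B in the interaction and PLIN2 with LDL), 72 moved with a pseudocount and 2 reversed. The reversed values were the CCL1 interaction, -1.17 with a pseudocount of 0.1 CPM and -1.23 with 1 CPM.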

Other observations

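The second lists, of tissue-resident-type, mature dendritic-type and zinc-responsive genes, were chosen only after the data were seen, and counts of their genes are no independent evidence.

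Markers of a tissue-resident-type macrophage were lower with LL37: of 10 genes in the authors' deposited table, 8 fell, 1 rose and 1 did not pass (median -2.01). With LDL 5 rose and 5 did not pass, and with LDL plus LL37 2 rose, 5 fell and 3 did not pass in the authors' deposited table. Against LL37 alone, 7 of 8 tested genes were higher with LDL plus LL37 and 1 did not pass (median 0.83). MAF, a transcription factor, was at 0.43 with LDL, -1.55 with LL37 and -0.72 with LDL plus LL37 in the authors' deposited table. Of 10 mature dendritic-type markers, 8 rose, 1 fell and 1 did not pass with LL37 and with LDL plus LL37 in the authors' deposited table (medians 2.03 and 1.84), and 1 of 8 had an interaction that passed. Of the tissue-resident-type genes, MAF, F13A1 and GAS6 were among those not looked at before the list was written; among the dendritic-type genes BIRC3 also stands in the NF-kB list and CD80 in the antigen presentation list. EBI3, a cytokine subunit, was at 3.39 in both, and FSCN1, an actin-bundling protein, fell to -0.70 with LL37 in the authors' deposited table.

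Zinc-responsive genes fell with LDL. MT1X was at -1.83, MT2A at -2.96 and SLC30A1, a zinc exporter, at -1.38 with LDL, and at -2.76, -2.64 and -2.56 with LDL plus LL37, in the authors' deposited table. MT1X had a mean under 1 CPM over the 4 groups, below the cutoff of the naming rule, so its ratios rest on low counts. With LL37 MT2A rose to 0.93, SLC30A1 fell to -0.20 and MT1X did not pass in the authors' deposited table. The rise of MT2A with LL37 did not pass when adjusted over the 3 listed metallothioneins alone. Less zinc available to the cells may be a candidate explanation: SLC39A10, a zinc importer that rises when zinc is scarce, was at 0.73 (0.60 to 0.87) with LDL. It was at 0.13 with LDL plus LL37, where it did not pass although MT2A and SLC30A1 were also low, and at -1.18 with LL37, in the authors' deposited table. Zinc was not measured, and the test rests on 1 gene. After removal of the GC and length trend SLC30A1 was at -1.25 (-1.38 to -1.11) with LDL.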
